A study of Chromolaena odorata with 2 samples.

How the data were processed

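Tag-based digital gene expression was measured in 2 libraries from stem bases of Chromolaena odorata, a shrub of the daisy family that roots readily from cuttings. Per the labels' protocols, shoots were divided into 5 cm cuttings with 1 bud each and planted in sand at about 26 °C and 50 to 70% relative humidity. The lowest 0.5 cm of the cuttings was sampled. The library labelled before cutting came from day 0, which the labels also give as 0 days after cutting. The library after cutting came from a mixture of material from day 3 and day 7, so these 2 days cannot be separated. Each group held 1 library, and the number of plants behind it was not given in the sources used here.

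Per the labels' protocols, mRNA was taken from 6 µg of total RNA on oligo(dT) beads and copied into cDNA. NlaIII, an enzyme that cuts at CATG, left on the beads the fragment from the last cut site to the poly(A) tail. Adaptor 1 was joined at CATG. MmeI then cut 17 bases further on, and adaptor 2 was joined at that end. The resulting 21-base tags were amplified for 15 PCR cycles and sequenced. Copies of a tag therefore stand for the transcripts that end in that fragment, with no correction for transcript length. The tags carried no molecular identifiers, so copies made by PCR cannot be told from independent molecules. Intervals of tag ratios and of shares of copies cover counting error only. Intervals of medians and those by bootstrap describe the spread over tags, pairs or sites, taken as unrelated. None covers variation between plants.

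The deposited files gave, for each distinct tag, a copy number (a raw count) and a TPM value. Recalculation showed that the authors' TPM was the copy number per 1000000 copies in the same file, to within 0.005, for all 562126 tags before and all 463800 tags after cutting. The counts were used here, and copies per 1000000 copies, here CPM, were recomputed from them. Every listed tag had 21 bases, started with CATG, held no unknown base and had at least 2 copies. A tag that is not listed can therefore have had 0 or 1 copy, and the filters and base calling behind the lists are not given in the sources used here. The libraries totalled 5441693 copies before and 5141988 copies after cutting, so a single copy corresponded to 0.184 and 0.194 CPM.

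No reference genome or transcript set was used here, so tags are reported by sequence without gene names or genome positions. The lists of auxin, wounding, cell wall and other genes planned for the case that transcripts were at hand were not run. In their place, 5 classes of tags were defined from the sequence alone: tags ending in 6 or more A, tags holding AATAAA, tags holding a second CATG, tags with at most 6 G or C among the 17 bases after CATG, and tags with at least 11.

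With 1 library per group no test between conditions was possible, and no p-value was computed. For each tag with at least 10 CPM in at least 1 library, the ratio after to before cutting was formed from CPM. Its exact 95% interval came from the binomial distribution of the after-cutting copies given the sum of both (Clopper-Pearson). A tag was called higher when the whole interval lay above 2 and lower when it lay below 1/2. In this interval, a tag that is not listed in a library was given 1 copy, the most it can have had. A ratio against such a tag is printed only as a lower bound computed against 3 copies in that library. Log2 ratios used for medians had 0.5 copies added in each library. Intervals of medians are exact order-statistic intervals, and shares of copies have exact Clopper-Pearson intervals. The median of each class is given relative to the median of all tested tags and was set against 10000 random lists of the same size, matched on mean abundance in 20 bins, as a description of these 2 libraries.

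The tags named are the 10 with the highest lower bound of the ratio, the 10 with the lowest upper bound, the 5 most abundant of each library and the 2 most abundant of each class. This rule, the classes, the thresholds and most alternatives were fixed before the data were examined. On data simulated from the pooled tag abundances, the procedure called in the right direction 100% of 50 tags raised 4-fold, of 50 raised 8-fold, of 50 lowered 4-fold and of 50 lowered 8-fold, among 15411 tags that passed the filter. It called 0 of 15211 unchanged tags. Their simulated ratio of 1 lay far inside the limit of 2, so calls among them were unlikely by construction. This simulation held counting error alone, without variation between plants. Its changed tags were drawn from abundances above the filter of 10 CPM, and their folds lay well beyond 2. Changes near either limit were therefore not checked. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Alternatives were scaling by TMM factors from edgeR 4.0.16 in R 4.3.3, by the median of ratios, and without the most abundant tags. The median of ratios to the geometric mean of both libraries was taken over the 44838 tags with at least 10 copies in each. Further alternatives were other filters, intervals and fold limits, and the merging of tags that differ at 1 base from a tag at least 20 times as abundant.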

Results

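Stem bases were profiled at 2 stages that the labels place in adventitious root formation, the growth of roots from stem tissue: before cutting and after it. The question the design addresses is which transcripts differ in abundance between these stages. The library before cutting held 562126 distinct tags in 5441693 copies, and the library after cutting held 463800 distinct tags in 5141988 copies. The median tag had 3 copies in each. Both libraries listed 251089 tags, 32.4% of the 774837 distinct tags seen in either. These shared tags held 80.8% of the copies before and 85.7% of the copies after cutting. All comparisons rest on 1 library per group, so they describe these libraries, and no difference has a replicate check.

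In the library after cutting, the copies were spread over fewer distinct tags. Thinned to 5141988 copies, the library before cutting kept 561443 distinct tags, 21.1% above the 463800 after cutting. Counting only tags with at least 2 copies, the rule the deposited lists follow, the number before cutting was 537672, or 15.9% above. The effective number of tags, the exponential of the Shannon entropy, was 101037 before and 79776 after cutting. Tags with more than 100 copies held 38.5% of the copies before and 43.1% after, whereas tags with 2 to 5 copies held 21.6% and 18.3%. The 100 most abundant tags did not follow this shift. They held 8.16% (95% interval 8.14 to 8.18) of the copies before and 7.52% (7.49 to 7.54) after cutting, and the lists shared only 25 tags.

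Few of the leading tags were shared between the stages. Tag CATGCAATCAATATGCATAAA was prominent at both stages, at rank 4 before cutting with 14866 copies and at rank 1 after it with 23884, a ratio of 1.70 (95% interval 1.67 to 1.74). The other leading tags before cutting were lower afterwards. CATGTCTTTTAAGTTTATGGA went from 22663 copies to 11, and CATGTCTTTTAAGTCTATGGA from 15063 copies to not listed. CATGAAGTTTGATTGATGTCA went from 17457 copies to 197, 83.7-fold lower (72.8 to 96.9). CATGAAAAACCAATTTATAAA differed least among these, from 13643 copies to 6122, 2.11-fold lower (2.04 to 2.17), and was still at rank 9 after cutting. Of the 100 most abundant tags before cutting, 72 were called lower after cutting, 1 was called higher and 27 were called neither.

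After cutting, the second most abundant tag was CATGTAATAAATAAAAGAAAC, with 1391 copies before and 20265 after, 15.4-fold higher (14.6 to 16.3). CATGCAGATTTTACCTTTAAC was at rank 3 and 37.8-fold higher (34.4 to 41.7), at 78.8 CPM before and 2981 after. CATGGTTTATTTTGTTGAAGC was at rank 4 and 10.6-fold higher (9.81 to 11.4). The fifth, CATGTCGGACTGTAGAACTCT, is no plant tag by its sequence. Its 17 bases after CATG are those of the lower strand of adaptor 1 in the NlaIII tag-profiling kit of Illumina, known from the kit and not from the labels. It held 0.0246% of the copies before and 0.146% after cutting. Of the 100 most abundant tags after cutting, 63 were called higher, 4 lower and 33 neither. Each list was chosen on the library in which its tags were abundant, so these counts are not independent of the choice.

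Among 18912 tags with at least 10 CPM in a library, 4970 were called higher after cutting, by more than 2-fold beyond counting error, and 3058 were called lower by the same rule. The remaining 10884 were called neither. The higher tags held 4.50% of the copies before and 24.5% (95% interval 24.5 to 24.6) of the copies after cutting. The lower tags held 19.7% (19.7 to 19.8) before and 3.02% after. The median tag called higher was 5.43-fold higher and the median tag called lower was 7.12-fold lower. In all, 529 of the higher tags were not listed before cutting and 344 of the lower tags were not listed after it. The balance of directions depended on the centre of the ratios. The median tested tag lay at a log2 ratio of 0.48 (-0.48 over all tags without the filter on low counts), and 61.9% of the calls were higher. Centred on that median, 3367 tags were higher and 4351 lower, 43.6% higher.

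**Figure D1:**
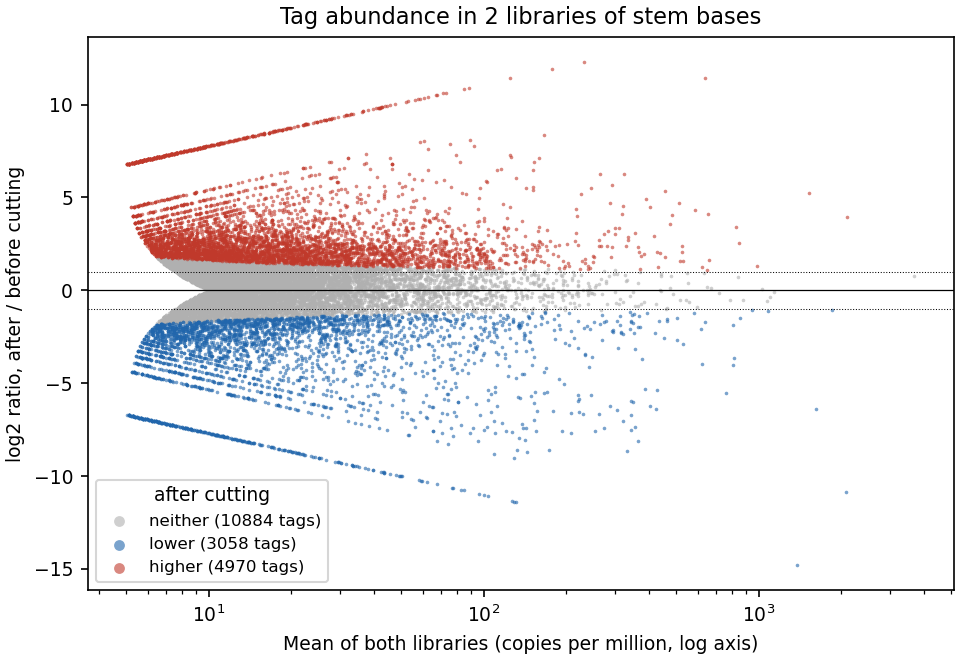
Log2 ratio after to before cutting of 18912 tags against their mean CPM (log axis), 1 library per group, with 0.5 copies added in each library. Red points are the 4970 tags called higher, blue points the 3058 called lower and grey points the 10884 called neither. Dotted lines mark 2-fold, and the slanted outer lines are tags not listed in 1 library.

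Calls were counted by abundance. A call needs an interval beyond 2-fold, so it is easier to reach with more copies. Between 10 and 50 CPM, 24.2% of 15880 tags were higher and 14.4% lower after cutting. Between 50 and 100 CPM, 36.9% of 1777 tags were higher and 21.4% lower. Between 100 and 500 CPM, 37.5% of 1130 tags were higher and 29.6% lower. Between 500 and 1000 CPM, 37.5% of 96 tags were higher and 43.8% lower. Among the 29 tags with at least 1000 CPM in a library, 9 were higher and 13 lower. These counts depend on the centre of the ratios as well.

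The 10 tags with the highest ratios together held 0.000129% of the copies before and 0.345% after cutting. The first was CATGAAGTTGTAATTTGAGCA, with 2 copies before and 6576 after, a ratio of 3479.6 with a wide counting interval of 963 to 28739. CATGAATTTCAATAAATATGA had 5 copies before and 1695 after, 359-fold higher (153 to 1106). The other 8 were not listed before cutting. Of these, CATGGTGGTGTACTAGTTCGA had 2378 copies after cutting, at least 839-fold higher, and CATGCTGTTAAAGTTTTTAAG had 1819, at least 642-fold higher. CATGTAATGTTTGTTGCATCT had 1284 copies and CATGATCACCATTTTACTAAA had 912. CATGCAAGTTACTATTCGTTT had 876 copies, CATGTCCCAGTACGAGATCGA 753, CATGCTTAATATGTAAAATAA 733 and CATGATGTTTTGACTCAACAA 696, the last at least 246-fold higher.

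The 10 tags with the lowest ratios held 0.923% of the copies before and 0.000408% after cutting. Most of this came from the tags CATGTCTTTTAAGTCTATGGA and CATGTCTTTTAAGTTTATGGA, which differ by C15T, counted from 1 at the first base of the tag. The C form was at least 4744-fold lower and the T form 1947-fold lower (1088 to 3900.4). CATGTTACAGAGAAAGATTCT went from 3598 copies to 8, 425-fold lower (215 to 985), and CATGAGAAACCTTTTAATCAT from 1401 copies to 2, 662-fold lower (183 to 5471). The other 6 were not listed after cutting. They were CATGGAAACCGGCAAATTCTT with 1433 copies before, CATGAAACAAATCTGTTGCAA with 1405, CATGGGGAGGAAGGCCCGAGA with 1379, CATGTTTTATCACATCCATAC with 1130, CATGTAAATTTTGTTTGTTTG with 1095 and CATGAAGATTGGAGTCGTTAC with 1046. These tags were at least 451-fold lower for the first and at least 329-fold lower for the last.

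**Figure D2:**
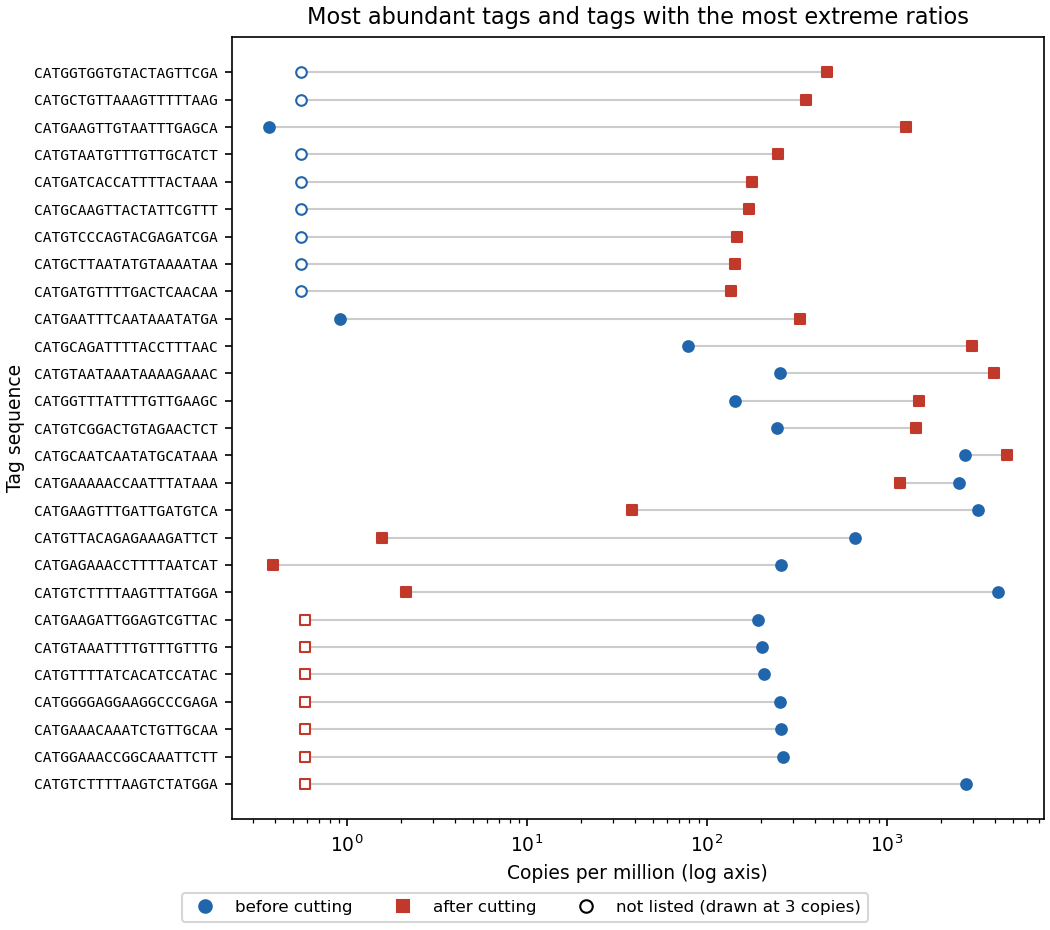
CPM (log axis) before cutting (blue circles) and after cutting (red squares) of the 5 most abundant tags of each library and the 10 tags with the most extreme ratio in each direction, 1 library per group. Open symbols are tags not listed in a library, drawn at 3 copies. CATGCAATCAATATGCATAAA had 2732 CPM before and 4645 after cutting, while CATGTCTTTTAAGTTTATGGA had 4165 before and 2.14 after cutting.

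Tags ending in 6 or more A stood apart from the rest. Such a run can be the start of the poly(A) tail or an A-rich stretch inside a transcript, which tags alone cannot tell. Of 684 tested, 280 were called higher after cutting, 55 lower and 349 neither. Their share of all copies was 2.17% before and 3.91% after cutting. Their median log2 ratio lay 0.74 above that of all tested tags (95% interval 0.61 to 0.85), outside the range of -0.36 to 0.38 over 10000 random lists of matched abundance. Both the interval and the lists treat tags as unrelated, which was not checked for this class. Without a filter on low counts the class median lay 1.84 above that of all tags. Only 32.4% of all tags were listed in both libraries, so most of those ratios rest on the 0.5 copies added. The most abundant members were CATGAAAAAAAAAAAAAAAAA, 1.87-fold higher (1.76 to 1.98), and CATGTTGATGTTAAAAAAAAA, 2.38-fold higher (2.24 to 2.54). Tags ending in exactly 2 A were also above the rest, by 0.39 (0.29 to 0.49), and tags ending in exactly 2 T were below it, by a median difference of -0.57 (-0.74 to -0.40). When ratios were centred within each pair of last bases, the difference of the class was 0.34. This value is inside the range of the random lists, but those were drawn from ratios without this centring, so the comparison decides nothing.

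**Figure D3:**
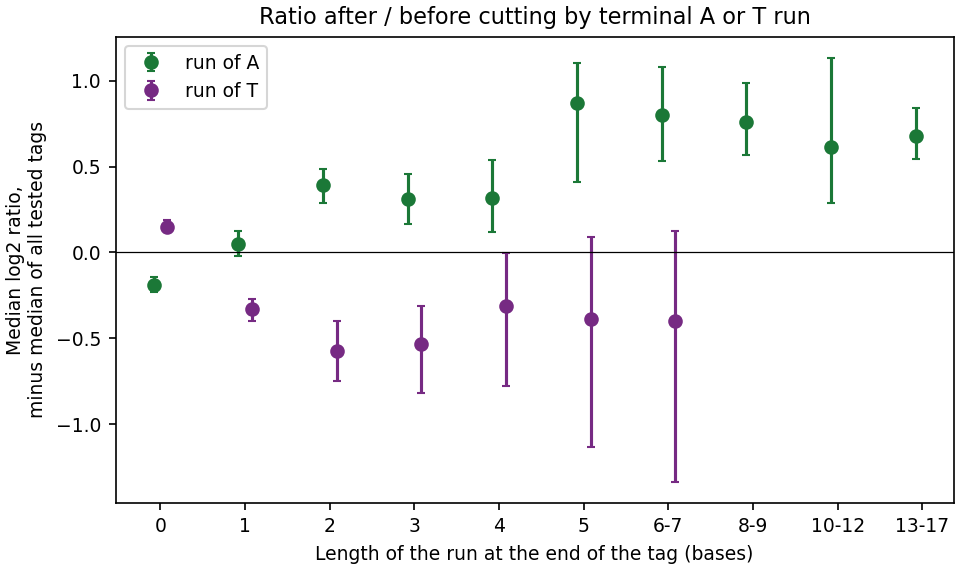
Median log2 ratio after to before cutting, minus the median of all 18912 tested tags, by the length in bases of the run of A (green) or T (purple) at the end of the tag. Bars are exact 95% intervals of the median over tags, with 1 library per group. Tags with 5 or more terminal A lay 0.61 to 0.87 above the rest, and medians of tags ending in T lay below it, with intervals that hold 0 for runs of 5 or more T.

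The class of tags with a second CATG had a lower share and a lower median after cutting, although most of its tags were called neither. Such a tag comes from a transcript that was left uncut at a CATG further on. The class held 0.628% (95% interval 0.622 to 0.635) of the copies before and 0.468% (0.462 to 0.474) after cutting. Of 82 tested, 12 were called higher, 20 lower and 50 neither, and the median log2 ratio relative to all tested tags was -1.14 (-1.39 to -0.57), or -0.54 without a filter on low counts and -1.50 at a filter of 50 CPM. Of 10000 random lists, which ranged from -1.16 to 0.95, 0.01% had a lower median. Over 182 double sites at most 5 bases apart, the pooled share of copies left uncut at the second site was 15.2% before and 10.96% after cutting, a ratio of 0.72 (0.45 to 1.17). This limit was chosen after the values were seen, and the ratio was 0.98 (0.63 to 1.45) at 4 bases, 0.59 (0.39 to 0.86) at 6 and 0.63 (0.43 to 0.90) at 9. CATGTCATGAATGTTGTTTCT went from 3470 copies to 372, 8.81-fold lower (7.92 to 9.84), whereas CATGCATGATGATGGTACAAT had 1322 and 1617 copies, a ratio of 1.29 (1.203 to 1.393).

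The medians of the other sequence classes lay within the range of the random lists as well, at percentile 25.7 for AATAAA, 7.04 for low GC and 91.9 for high GC. Of 373 tested tags holding AATAAA, the canonical polyadenylation signal, 100 were called higher and 55 lower, and the median relative to all tags was -0.09 (-0.30 to 0.10). Its leading members were CATGTAATAAATAAAAGAAAC, given above, and CATGTACGTCTAAATAAACAC, with 3295 and 3550 copies. Of 12784 tags with low GC content, 3389 were higher and 2074 lower, with a relative median of -0.02 (-0.05 to 0.02). The most abundant of these, CATGCAATCAATATGCATAAA and CATGTCTTTTAAGTTTATGGA, are given above. Of 310 tags with high GC content, 85 were higher and 49 lower, with a relative median of 0.16 (-0.19 to 0.38). The most abundant of these were CATGGGGGTGGTGAAGGGAGG, with 3308 and 2189 copies, and CATGTGGTGGCTGTGTTGGGG, with 1147 and 1986. The median of the AATAAA class turned positive (0.18) without a filter on low counts, and that of the high GC class turned negative (-0.68) at a filter of 50 CPM.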

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

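Alternatives named as later choices were chosen after seeing the data. No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out. Over the alternatives of scaling, of merging and of the interval, the higher tags numbered 3367 to 5265 and the lower tags 2422 to 4351. The counts moved by more than 1.5 times without a filter (10930 higher, 6956 lower), with a filter of 50 CPM (1125 and 771) and with the interval beyond 4-fold (2123 and 1620), which by construction test other numbers of tags or ask for a larger ratio. The shares of copies in the higher tags (after cutting) and lower tags (before cutting) were 27.6% and 21.7% without a filter, 16.01% and 14.7% at 50 CPM, and 12.5% and 12.3% beyond 4-fold. They were 25.6% and 18.7% with TMM, 22.5% and 21.1% with the median of ratios, 24.8% and 19.95% with possible errors merged, and 21.3% and 18.0% with the stricter counting interval. Under later choices they were 18.3% and 24.7% centred on the median tested tag, 24.4% and 18.8% centred within the last 2 bases, and 23.4% and 19.5% without tags ending in 6 or more A, and the share of the higher tags was 24.4% without adaptor tags. The median of ratios shifted the median log2 ratio of all tested tags by -0.15, and 56.5% of calls were then higher. Without a filter, that median turned from 0.48 to -0.48. Scaling by the total of tags with at least 2 copies changed nothing, since the lists hold no others. Without a filter, the class medians relative to all tags were 1.84 for terminal A, 0.18 for AATAAA, -0.54 for a second CATG, -0.089 for low GC and 0.56 for high GC. Most tags are then listed in only 1 library, so most ratios behind these medians rest on the 0.5 copies added. The cause of these shifts was not tested. At 50 CPM they were -1.50 for a second CATG and -0.68 for high GC, and centring within the last 2 bases gave 0.34 for terminal A. The 100 most abundant tags held 8.30% before and 7.66% after cutting with errors merged and 7.42% after cutting without adaptor tags, the 10 most abundant held 2.27% and 2.08%, and the 1000 most abundant shared 390 tags. Thinned to 1000000 copies, the libraries held 300315 distinct tags before and 254370 after cutting. Depth limits the precision of tags near 10 CPM, which rest on about 50 copies, and cannot show a tag with fewer than 2.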

Other observations

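The tests of abundance, of substitution errors, of digestion in both classes it is set against and of the terminal A class against tags ending in AA were chosen after the results they bear on were seen, whereas the test on pairs that differ in the last base was set before its result. Many tested tags had a close relative in sequence with a similar ratio. Leaving out tags that end in 6 or more A, there were 2634 pairs of tested tags that differ at a single base and whose rarer member has at least 10% of the copies of the commoner. They held 4643 tags, 24.6% of those tested. Both members were called in the same direction in 974 pairs and in opposite directions in 9, and 486 pairs had 1 member called. CATGCAGATTCTACCTTTAAC and CATGCAGATTTTACCTTTAAC, which differ by C11T, were 40.8-fold (95% counting interval 34.0 to 49.3) and 37.8-fold (34.4 to 41.7) higher after cutting. CATGTTCATCGCTGCCAAACC and CATGTTTATCGCTGCCAAACC (C7T) were 201-fold (117 to 378) and 165-fold (109 to 263) lower, and CATGTCGTGTGATTGTGTGGA and CATGTTGTGTGATTGTGTGGA (C6T) were 126-fold (73.6 to 238) and 67.2-fold (43.8 to 109) higher. Positions count from 1 at the first base of the tag, and these pairs were picked after their values were seen.

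The 9 opposite pairs are the exceptions. CATGGGTTTTACAAGTATTGA went from 246 copies to 1305, 5.61-fold higher (4.90 to 6.46), while CATGGGTTTTCCAAGTATTGA (A11C) went from 1375 copies to 49, 26.5-fold lower (19.9 to 36.0). CATGCTGTATCTGAAGGTACT was 4.02-fold lower (3.52 to 4.60), while its relatives CATGCTGTTTCTGAAGGTACT (A9T) and CATGCTGTGTCTGAAGGTACT (A9G) were 3.11-fold (2.64 to 3.67) and 2.40-fold (2.01 to 2.87) higher. CATGCTCATTGCACCGTGATG was 5.72-fold higher (4.68 to 7.05), and CATGCTCATTGCACTGTGATG (C15T) was 2.55-fold lower (2.10 to 3.12).

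Across the 2634 pairs, the log2 ratios of the members had a Pearson r of 0.898 and a Spearman rho of 0.905, over tags, which are not independent replicates. Similar abundance alone was argued against, since the highest r over 1000 random pairings matched on abundance was 0.101, and these pairings gave a median of 259 opposite pairs. Substitution errors of a tag read as another, at the same rate in both libraries, would give both members the same ratio. The 95% ratio intervals of the members did not overlap in 525 of 2634 pairs, 19.9% (18.4 to 21.5). These intervals leave out copies made by PCR, and some tags are in more than 1 pair. This share alone therefore cannot exclude errors as the source of all pairs. Whether errors are the source of most pairs stays open. Among 261 pairs with a member at 200 CPM or more, taken from 2764 pairs at any share of the rarer tag, the rarer tag was within the error range in 18.0% (13.5 to 23.2) when that range came from the library before cutting, at most 5.22% of the commoner tag, and in 64.4% (58.2 to 70.2) when it came from the library after cutting, at most 28.6%. Only tags that passed the filter at 10 CPM could enter these pairs. These tests of errors are the last 2 of 3 tried. The first used the median share of the rarer tag, 57.7% over the 2634 pairs. Set against the range of 5.22%, its result was fixed in advance, because the pairs were chosen at 10% or more. Set against 28.6%, it was not fixed by that choice. Both members had to pass the filter, though, and 15880 of 18912 tested tags peaked between 10 and 50 CPM. Near the filter, only partners at a large share could enter. In the 261 pairs with an abundant member, the median share was 16.7%. The median over the 2634 pairs therefore decides nothing about errors as their source. Both ranges were the 99th percentile of the share held by single 1-base neighbours of tags with at least 2000 copies. True relatives were not left out of them. Of these neighbours, 0.84% before and 1.42% after cutting held over 10% of their tag. The ranges may therefore be set by such relatives and are no measured error rate. The error range was at first taken from the library before cutting alone, and the other was added after that result. Besides errors, a candidate explanation is that such pairs are alleles or gene copies with shared control, with the opposite pairs as copies that part, or that plants of different genotype entered the libraries. That was not tested and needs transcript sequences.

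Tested tags ending in A lay higher in the library after cutting as a group, by 0.27 (0.22 to 0.31), and those ending in T lay lower, by -0.39 (-0.45 to -0.33). Most pairs of last bases followed this, with AA at 0.39 (0.29 to 0.49), CA at 0.37 (0.24 to 0.45) and TA at 0.16 (0.02 to 0.25), and with GT at -0.84 (-1.01 to -0.69), CT at -0.53 (-0.72 to -0.28) and TT at -0.51 (-0.67 to -0.39). Here AA leaves out tags with longer runs of A, while TT includes tags with longer runs of T. The exceptions were GA, which lay lower (-0.38, -0.51 to -0.24), and AT, at -0.07 (-0.16 to 0.02). Tags with exactly 1 terminal A were at 0.05 (-0.02 to 0.12). The intervals of these groups treat tags as unrelated. Since 24.6% of the tested tags were in the 1-base pairs above, the intervals may be too narrow. A preference for the last 2 bases alone when adaptor 2 was joined was argued against as the whole cause of the terminal A class. The class lay 0.35 (0.19 to 0.50) above tags ending in exactly AA on the log2 scale. A preference that reaches further into the tag was not tested. As a source of the general trend, a preference for end bases stays open. In 73 pairs that differ only in the last base, the A form exceeded the T form by a median of 0.21 (-0.01 to 0.45), with 44 of 73 in that direction. A against T at bases 6 to 19 gave -0.10 (-0.17 to 0.02) over 384 pairs. Of 24 such contrasts computed, without adjustment for their number, 2 had an interval clear of 0. These were C against T at base 21, 0.48 (0.27 to 0.84) with 33 of 39 pairs, which goes with the lower tags ending in T, and C against T at base 5, next to adaptor 1, 0.29 (0.08 to 0.52) with 40 of 60 pairs. More complete NlaIII digestion also stays open: over 182 double CATG sites at most 5 bases apart, the pooled share of copies left uncut at the second site was 15.2% before and 10.96% after cutting, a ratio of 0.72 (0.45 to 1.17 by bootstrap over sites). Whether the interval held 1 depended on this limit: the ratio was 0.98 (0.63 to 1.45) at 4 bases, and 0.59 (0.39 to 0.86), 0.56 (0.38 to 0.82), 0.58 (0.40 to 0.82) and 0.63 (0.43 to 0.90) at 6, 7, 8 and 9 bases, where matches to other tags by chance are more common. Even full digestion would raise the cut share there by only 1.18 times, so these sites cannot show the 1.67-fold by which the terminal A class stood above the rest, and sites near a run of A were not measured apart. A real difference in transcripts or in their 3' ends between the stages also stays open and was not tested, since stage and library are the same split.

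Tags with a second CATG at most 5 bases on could be set against the cut tag of the same site, matched on at least 16 bases. For 42 tested tags of this kind, the uncut tag was lower against the cut tag by a median log2 ratio of -0.96 (-1.45 to -0.36), with 33 of 42 in that direction, while their own median relative to all tested tags was -1.18 (-1.55 to -0.57). Allowing up to 9 bases, where matches by chance are common, gave -1.18 (-1.58 to -0.73) over 60 tags, and the limit of 5 was set after those values were seen. More complete digestion is therefore a candidate explanation for the lower level of this class. For double sites as a whole the pooled ratios above do not agree, and a real difference in these transcripts stays open.

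Tags with C directly after CATG, next to adaptor 1, held 17.4% of the copies before and 22.7% after cutting, and their median log2 ratio was 0.45 (0.39 to 0.51) above that of all tested tags. The 813 tags that start with the first 12 bases of the adaptor tag, CATGTCGGACTG, held 0.0331% of the copies before and 0.199% after cutting, a ratio of 6.00.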
